A study of Mus musculus with 26 samples.

How the data were processed

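RNA was measured by sequencing in 26 samples of mouse ear skin, each from part of an ear kept in a stabilising solution, per the labels' protocols. All mice had received MC903, a vitamin D analogue that causes inflammation of the skin, at 1.5 nmol every 2 to 3 days for 17 days. Recombinant human IL-26 (200 ng) or bovine serum albumin (BSA) was injected into the ear skin every 2 days, and an antibody that neutralises IL-1β or a control IgG was given into the peritoneum at 10 mg/kg every 5 days. Libraries were made from 200 ng of total RNA after removal of ribosomal RNA with a stranded kit, per the labels' protocols. The groups were BSA with IgG (6 samples), IL-26 with IgG (6), BSA with anti-IL-1β (7) and IL-26 with anti-IL-1β (7). No sample without MC903 was analysed here.

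The authors deposited one table of estimated counts per gene, not normalized, for 56200 genes and all 26 samples. Of the values above 0, 31.5% were not whole numbers at a tolerance of 1e-06, which means that reads shared between genes had been divided among them. Reads were aligned with STAR 2.7.3a to the mouse genome GRCm38, per the submitters' processing notes; the counting program, the release of the annotation and the strand setting are not given in the sources used here. Gene names and coordinates were taken from the GENCODE vM21 annotation of GRCm38, which named 55240 of the gene identifiers. The 960 identifiers without a name held 0.0223% of the counts. Genes that overlap another annotated gene, such as Pitx1, Spink7, Slurp1, Flg, Mrc1, Il4ra, Cyp24a1, Dct and mt-Atp6, and near-identical genes such as Gsta1 and Gsta2, have values that the division of reads could have changed, and they are uncertain to that extent.

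The counts were rounded to whole numbers and analysed in R 4.3.3. Total counts were 17114364 to 33541991 per sample. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), which left 19576 genes. A quasi-likelihood model of edgeR 4.0.16 with TMM normalization was fitted to all samples at once, with 1 mean per group, and 5 contrasts were tested: IL-26 against BSA with IgG, IL-26 against BSA with anti-IL-1β, anti-IL-1β against IgG with BSA, anti-IL-1β against IgG with IL-26, and the difference between the first and the second, called the interaction. The p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and every adjusted p of a single gene below comes from this test. A count of samples higher or lower gives those of the first-named group whose log2 CPM lay on that side of the other group's mean, so single samples of both groups can overlap. Values after ± are standard errors for log2 fold changes and SD for group means. Levels are CPM from edgeR, counts relative to the library total scaled by TMM.

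The groups, the contrasts, the tests, 32 gene lists and the rule for naming genes were fixed before the data were examined. A list's score in a sample was the mean log2 CPM (prior count 2) of its measured members. Scores were compared by an exact two-sided permutation test over all splits of the samples, or, for the interaction, by 100000 permutations of residuals, and adjusted over the 32 lists. Genes were named by rule: in each contrast the 10 largest increases and 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 0 and a symbol that is not of the predicted kind, up to 4 members of each list described, and 21 genes in any case. Of these, the text gives the values that matter for each comparison. Some genes belong to more than 1 list.

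Simulated data were used to test the procedure: counts were drawn for all 19576 genes with 100 genes changed 1.5-fold and 100 changed 2-fold. For IL-26 with IgG, 76% and 87% of these were recovered, and 3.55% of the calls were false. The shares recovered were 60% and 92% for IL-26 with anti-IL-1β (2.56% false), 68% and 86% for anti-IL-1β with BSA (9.41% false), 73% and 89% for anti-IL-1β with IL-26 (4.14% false), and 47% and 77% for the interaction (1.57% false). Each contrast had 1 run, in which genes were drawn independently and no library stood apart. The real data need not meet these conditions, so the shares describe the simulation only.

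Of the other analyses 13 were planned, besides leaving out each library in turn: RLE size factors, no filter, a mean CPM of at least 1, DESeq2 1.42.0, limma 3.58.1 (voom with sample weights), robust dispersions, a fit of only the groups compared, a block for the replicate number, and, for lists, camera with a preset (0.01) and an estimated correlation, fry, z scores and a prior count of 0.5. A further 6 were added after the data had been seen, and all are reported: 1 library in place of IL-26 IgG replicates 1 and 2, protein-coding genes only, and as covariates the circadian score, the immediate-early score, the small RNA share and the log2 CPM of Cyp24a1. The limits used to judge the first 3 covariates were set after their counts of genes had been seen, and those for Cyp24a1 and for the share of epidermis before their results. Other splits of the samples were limited to 40 per contrast because of computing time.

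Libraries were compared pair by pair before averaging. IL-26 IgG replicates 1 and 2 had a chi-square of 1.82 per gene, against 5.50 for the next closest of the 325 pairs and a median of 21.9. This does not show whether they came from 1 ear or 1 RNA; they were kept as 2 libraries because the labels list 2 samples, and were also analysed as 1. The labels do not say that each sample came from another animal, so p-values measure the spread between these samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out, and reads were not aligned again.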

Results

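Ear skin of 26 MC903-treated mouse samples was profiled by RNA sequencing in 4 groups that combine an injection (IL-26 or BSA) with an antibody (IgG or anti-IL-1β). There were 6 samples of BSA with IgG, 6 of IL-26 with IgG, 7 of BSA with anti-IL-1β and 7 of IL-26 with anti-IL-1β. Libraries held 17114364 to 33541991 counts. IL-26 is a human cytokine of the IL-10 family whose receptor is formed by IL20RA and IL10RB, and IL-1β is a central cytokine of early inflammation.

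The first comparison asked what IL-26 did to inflamed skin while IL-1β could act. With IgG, the score of the type 2 inflammation list rose with IL-26 and that of the melanocyte and nerve list fell (exact permutation, adjusted p = 0.0346 and 0.0462). However, camera with an estimated correlation gave adjusted p = 0.201 for both. Camera compares the genes of a list with all other genes, and the permutation compares sample scores between groups, so they answer different questions. Every later adjusted p with an estimated correlation is from camera. Ccl24, which attracts eosinophils, rose from 8.92 ± 3.64 to 31.3 ± 30.6 CPM, and its log2 fold change of 1.81 was 1.08 without IL-26 IgG replicate 4 (edgeR adjusted p = 0.0445). Col6a5, a collagen VI chain, rose from 17.8 ± 4.72 to 69.3 ± 30.0 CPM (SD, n = 6 and 6). Serpinb12, a protease inhibitor of the epidermis, fell from 53.7 ± 13.3 to 15.6 ± 4.08 CPM. In edgeR's test 1693 of 19576 genes passed the threshold, 848 higher and 845 lower, and 55 and 67 of them by 2-fold or more.

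Of the 21 measured members of the type 2 list, 7 rose and 0 fell; adjusted over the list alone, 11 were higher and 1 lower. The list's score rose by 0.55 (exact permutation, adjusted p = 0.0346), although adjusted p = 0.201 with an estimated correlation. Il1rl1, the receptor of IL-33, rose by 0.97 ± 0.23 (log2; adjusted p = 0.00931; higher in 5 of 6 samples), and Mrc1, the mannose receptor of macrophages, by 0.88 ± 0.21 (adjusted p = 0.0119; 6 of 6). Il4ra, the receptor chain shared by IL-4 and IL-13, rose by 0.75 ± 0.20 (adjusted p = 0.0197; 6 of 6). That call was lost without BSA IgG replicate 2 or 3 or IL-26 IgG replicate 4 (adjusted p up to 0.0730). The cytokines themselves did not pass: the log2 fold change was −0.20 for Il4, 0.49 for Il13 and 0.25 for Il33. Of 18 monocyte and macrophage genes 6 rose and 0 fell (12 and 0 adjusted over the list alone), among them the macrophage receptor Adgre1 (0.53 ± 0.14; call lost without BSA IgG replicate 3, adjusted p = 0.0514). The score difference of 0.40 did not pass (adjusted p = 0.0577).

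Of the 28 measured epidermal barrier genes 13 fell and 1 rose, or 19 and 1 adjusted over the list alone, while the score difference of −0.33 did not pass (adjusted p = 0.0577). The desmosomal cadherin Dsg1a fell by 0.67 ± 0.10 (adjusted p = 0.000635), the keratins Krt10 by 0.94 ± 0.17 and Krt1 by 0.54 ± 0.10, and filaggrin (Flg) by 0.75 ± 0.16 from 8800 to 5224 CPM, each lower in 6 of 6 samples. The decreases with the greatest log2 fold change were in the homeobox gene Pitx1 (−3.09 ± 0.49), the epithelial metallothionein Mt4 (−2.73 ± 0.38), Spink7 (−2.40 ± 0.50; −3.02 without IL-26 IgG replicate 2), Serpinb12 (−1.78 ± 0.19; adjusted p = 1.67e-05) and the keratinocyte-secreted Slurp2 (−1.75 ± 0.33). Serpinb12 lies on chromosome 1 at 106934449 to 106957080 and Col6a5 on chromosome 9 at 105856078 to 105960643 (GRCm38). The greatest increases were in Retnlg, a resistin-like gene of neutrophils (2.01 ± 0.44), Col6a5 (1.95 ± 0.30), Ccl24 (1.81 ± 0.42; 1.08 without IL-26 IgG replicate 4), the carbonic anhydrases Car4 (1.73 ± 0.34) and Car9 (1.55 ± 0.22), and Chil3 (1.67 ± 0.40), which lost its call without IL-26 IgG replicate 4 (1.05; adjusted p = 0.0608).

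The melanocyte and nerve list fell by 0.36 (7 of 14 members lower, 8 adjusted over the list alone; exact permutation, adjusted p = 0.0462), although adjusted p = 0.201 with an estimated correlation. The members that fell with the smallest p were the pigment genes Dct (−0.75 ± 0.11), Pmel, Tyrp1 and Tyr. The list of immediate-early and heat shock genes, which respond to handling of tissue as well as to signals, fell by 0.41 (9 of 16 lower, 10 adjusted over the list alone; exact permutation, adjusted p = 0.0346), although adjusted p = 0.201 with an estimated correlation. Dusp1 fell by 0.82 ± 0.17 and Hspb1 by 0.69 ± 0.15. Of the 14 genes of the IL-26 receptor list 2 rose and 2 fell. Il20ra rose by 0.40 ± 0.11 (adjusted p = 0.0272), a call lost in 6 of the 12 fits without a library, and Il10rb differed by 0.22 (adjusted p = 0.179). Il20rb fell by 0.71 ± 0.16 (adjusted p = 0.00716), a call kept without each library, and Il22ra1 by 0.31 ± 0.09 (adjusted p = 0.0352; call lost in 7 of the 12 fits).

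The other lists did not pass in this comparison, with exact permutation adjusted p from 0.0577 to 0.792. The smallest p this test can give with these samples is 0.00216, at which a list alone would not pass the adjustment over 32 lists. Both the type 2 and the immediate-early list were at that value, so the resolution of the test limits what a list that did not pass can show. Score differences of immune lists were 0.56 for cytotoxic cells, 0.29 for T cells, 0.78 for eosinophils, 0.23 for antigen presentation, 0.48 for neutrophils, 0.27 for B cells and −0.024 for mast cells. They were 0.62 for type 1 interferon, 0.29 for interferon gamma, 0.044 for the IL-1 family, 0.12 for the response to IL-1 and NF-kB, 0.16 for IL-17 and IL-22, 0.043 for the IL-26 receptor, 0.26 for antimicrobial peptides, 0.19 for itch mediators and 0.32 for vitamin D response. For tissue lists they were 0.17 for keratinocyte activation, −0.021 for proliferation, 0.17 for extracellular matrix, 0.20 for endothelium, 0.21 for skeletal muscle, −0.14 for adipocytes, −0.043 for cartilage, −0.11 for sebaceous glands, 0.46 for hair follicle, 0.17 for blood and −0.095 for circadian genes. Of the genes followed in every comparison, Tslp, an epidermal cytokine that MC903 induces, differed by 0.94 ± 0.40 (adjusted p = 0.144; 0.0318 without BSA IgG replicate 4). Cyp24a1, the vitamin D hydroxylase that active vitamin D induces, differed by 0.74 ± 0.26 (adjusted p = 0.0716; past the threshold without BSA IgG replicate 4). Values that did not pass were −0.037 for Il1b, 0.32 for Il1a (adjusted p = 0.0469 without BSA IgG replicate 4), −0.055 for Il1rn, 0.22 for Il1r1, 0.098 for Ccl17, 0.15 for Ccl22, 0.083 for S100a8, 0.095 for S100a9, −0.18 for Cxcl1, −1.53 for Cxcl2 (adjusted p = 0.0537), 0.15 for Krt6a, −0.037 for Krt16 and −0.037 for the proliferation marker Mki67.

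The count of 1693 genes became 824 without BSA IgG replicate 3, 892 without BSA IgG replicate 2, 938 without IL-26 IgG replicate 4, 1055 without IL-26 IgG replicate 3 and 2590 without IL-26 IgG replicate 6. It was 3552 with limma and 13 with the immediate-early score as a covariate, where fold changes had a median ratio of 0.963 and the median standard error went from 0.101 to 0.141. With fry 10 of the 32 lists passed, with these 3 among them. Of the 3 lists, 0 passed without BSA IgG replicate 3 or 5. Without IL-26 IgG replicate 6, 9 of the 32 lists passed, with these 3 among them. The melanocyte list passed in 4 of the 12 fits without a library.

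**Figure D1:**
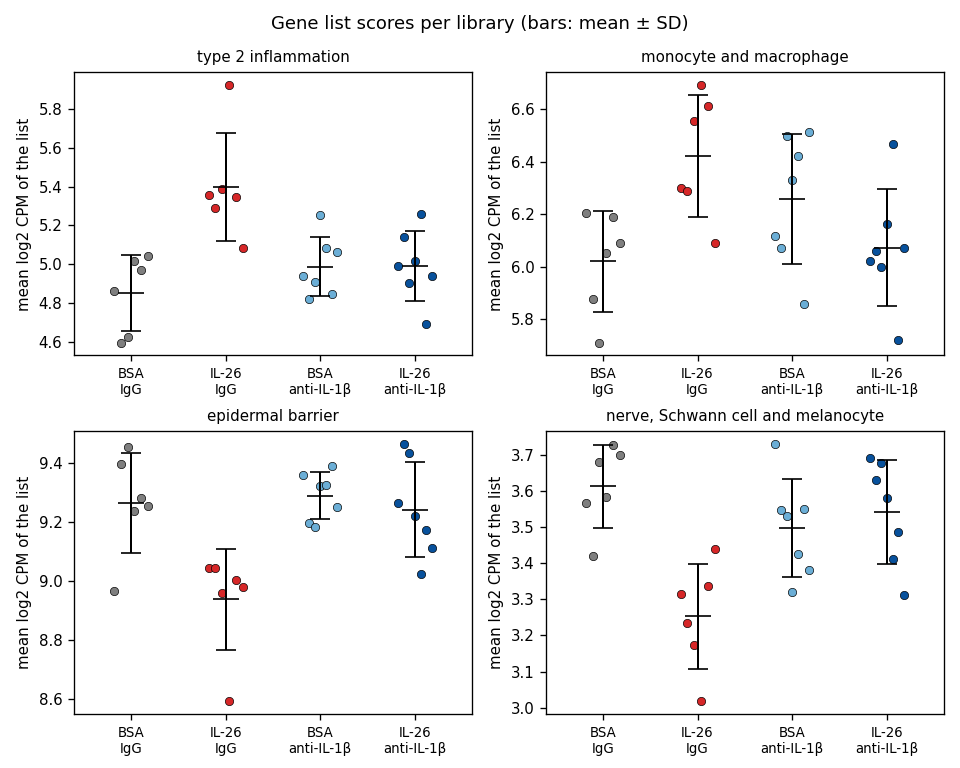
Score of 4 gene lists (mean log2 CPM of the measured members, y axis) in each library of the 4 groups (x axis); points are libraries and bars are mean ± SD. The type 2 score was 4.85 ± 0.20 with BSA and 5.399 ± 0.279 with IL-26 in the IgG groups, and 4.99 in both anti-IL-1β groups.

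The second comparison asked what IL-26 did in ears of samples given the antibody against IL-1β. With anti-IL-1β, 8 genes rose with IL-26 and 0 fell. Mt-Atp6, a mitochondrial subunit of ATP synthase (chromosome M, 7927 to 8607), rose from 128 ± 11.3 to 180.5 ± 27.0 CPM (log2 fold change 0.49 ± 0.08; adjusted p = 0.00818; higher in 7 of 7 samples). Zfp995 rose by 0.74 ± 0.14, and Dcun1d1, Vps13a and Rab18 by 0.27, 0.26 and 0.23, each at adjusted p = 0.0416. The other 3, named here although their predicted symbols fall outside the rule and chosen after their values were seen, were Gm10925 (0.50 ± 0.08), Gm23262 (1.59 ± 0.27) and Gm13341 (0.49 ± 0.09). Genes with sequence like that of mt-Atp6 can share its reads. The share of counts on mitochondrial genes was 1.42 ± 0.16% with BSA and 1.76 ± 0.17% with IL-26 (n = 7 and 7; exact permutation p = 0.00583, adjusted p = 0.0233).

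Genes called with IgG did not pass here: Col6a5 differed by 0.83 ± 0.28 (adjusted p = 0.212), Serpinb12 by 0.086 ± 0.17 (adjusted p = 0.868) and Flg by −0.23 ± 0.15. Tslp, called in neither antibody group, differed by −0.099 ± 0.38. The type 2 score differed by 0.0041 (4.99 in both groups), and 0 of its 21 members were called. None of the 32 lists passed the exact permutation test (smallest adjusted p = 0.533), where fry and camera with an estimated correlation gave 0 and camera with a preset correlation 9. The unadjusted p was below 0.05 for the circadian list, with a difference of 0.21 and exact permutation p = 0.0332. The hair follicle list, of keratins of the hair shaft and root sheath, differed by 1.21 (adjusted p = 0.533), with 16 of 22 members higher adjusted over the list alone and 0 over all genes. Krt81 differed by 4.45 ± 1.06 (adjusted p = 0.0766) and Krt83 by 4.22 ± 0.97 (adjusted p = 0.0746). Without IL-26 anti-IL-1β replicate 1 these were 2.43 and 2.06, and without BSA anti-IL-1β replicate 5 Krt81 was at 5.29. Krt83 passed without IL-26 anti-IL-1β replicate 5 (adjusted p = 0.0448). Scores of that list ranged from −0.32 to 5.08 within the IL-26 anti-IL-1β group, with the highest in replicate 1.

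At an unadjusted p under 0.05 there were 2434 genes, or 12.4% of those tested, against 24.9% for IL-26 with IgG. This is above the share of 0.05 that no effect gives on average, so the count of 8 does not show an absent effect. The count of 8 was 154 with DESeq2, 70 with limma, 4 without a filter, 1 among protein-coding genes and 0 in a fit of these groups alone. It was 3, 2, 2, 56, 4, 27 and 2 without BSA anti-IL-1β replicates 1 to 7 in turn, 75, 25 and 49 without IL-26 anti-IL-1β replicates 1, 3 and 5, and 2 without IL-26 anti-IL-1β replicate 4, 6 or 7; mt-Atp6 stayed past the threshold in each such fit.

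The third comparison asked what the antibody against IL-1β changed in BSA ears. No gene passed in edgeR (smallest adjusted p = 0.199), with 1370 genes (7%) at an unadjusted p under 0.05, and the count was also 0 with DESeq2 and with limma. Interferon-induced genes had some of the greater differences: the type 1 interferon score differed by 0.75 (exact permutation p = 0.0402, adjusted p = 0.322) and the interferon gamma score by 0.68 (adjusted p = 0.421). Cmpk2 was at 0.89 ± 0.28 (adjusted p = 0.631; higher in 7 of 7 samples). Casp1, the protease that matures IL-1β, differed by 0.39 ± 0.11 (adjusted p = 0.551) and the immediate-early gene Fos by −0.81 ± 0.20 (adjusted p = 0.551). Il1b itself differed by 0.33 ± 0.39, Il1rn, the receptor antagonist, by 0.22 ± 0.09, Tslp by −0.49 ± 0.39, Cyp24a1 by −0.34 ± 0.25 and Flg by 0.092 ± 0.16. The score of the response to IL-1 and NF-kB differed by 0.046 (exact permutation p = 0.818, adjusted p = 0.99), and 0 of its 26 members were called.

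No list passed by exact permutation (smallest adjusted p = 0.317, for the IL-26 receptor list with a difference of 0.16), and 4 of the 32 had an unadjusted p under 0.05: that list, type 1 interferon, cytotoxic cells (0.47) and immediate-early genes (−0.23). The estimated correlation and fry gave 0 lists and camera with a preset correlation 12. The count of genes was 7 without BSA anti-IL-1β replicate 4 and 1 without replicate 1 of that group.

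The share of counts on genes of small RNAs was lower in both anti-IL-1β groups, at 4.71 ± 0.32% against 5.75 ± 0.53% in BSA ears (n = 7 and 6; exact permutation p = 0.00117, adjusted p = 0.00936). It was 4.49 ± 0.42% against 5.63 ± 0.74% in IL-26 ears (n = 7 and 6; exact permutation p = 0.000583, adjusted p = 0.00700). The share on protein-coding genes was 1.22 and 1.21 percentage points higher (exact permutation, adjusted p = 0.00700 and 0.0210).

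**Figure D2:**
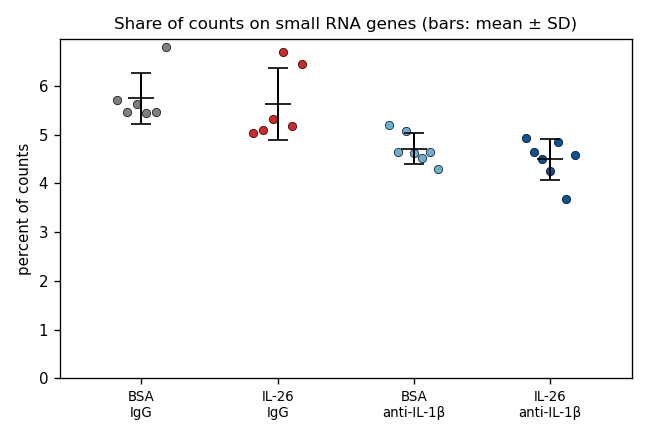
Share of counts on small RNA genes (percent, y axis) in each library of the 4 groups (x axis); points are libraries and bars are mean ± SD. Means were 5.75% and 5.63% in the IgG groups and 4.71% and 4.49% in the anti-IL-1β groups.

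The fourth comparison asked what the antibody against IL-1β changed in ears that received IL-26. Scores of vitamin D response and type 2 inflammation fell with anti-IL-1β, and those of the epidermal barrier, melanocytes and nerve, and the circadian clock rose (exact permutation, adjusted p = 0.0218 to 0.0293), although adjusted p = 0.391 for each with an estimated correlation. Tslp fell from 192 ± 50.4 to 66.3 ± 36.9 CPM and Cyp24a1 from 4675 ± 823 to 1909 ± 864 CPM (SD, n = 6 and 7), and Mmp13, a collagenase, from 112 ± 23.7 to 31.8 ± 18.2 CPM. Dsg1a rose from 650 ± 64.7 to 1095 ± 130 CPM. In edgeR's test 2828 genes passed, 1505 higher and 1323 lower, of which 109 and 90 by 2-fold or more. The mitochondrial share was 0.32 percentage points higher (exact permutation, adjusted p = 0.0224), against 0.048 points in BSA ears (adjusted p = 0.958).

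Of the 7 vitamin D response genes 3 fell and 1 rose (the same adjusted over the list alone), and the score fell by 0.66 (exact permutation, adjusted p = 0.0218), although adjusted p = 0.391 with an estimated correlation. The median log2 fold change of the 7 genes was −0.081, so the score fell through a few of them. Tslp fell by 1.54 ± 0.39 (log2; chromosome 18, 32815383 to 32819797; adjusted p = 0.00874), Cyp24a1 by 1.29 ± 0.25 (chromosome 2, 170482708 to 170497145; adjusted p = 0.00103) and the calcium-binding S100g by 2.18 ± 0.49, each lower in 7 of 7 samples. With the log2 CPM of Cyp24a1 as a covariate Tslp was at 0.17 (adjusted p = 0.832). The calcium channel Trpv6 rose by 0.60 ± 0.20. The type 2 list fell by 0.41 (6 of 21 lower and 1 higher, 9 and 1 adjusted over the list alone; exact permutation, adjusted p = 0.0218), although adjusted p = 0.391 with an estimated correlation. Il4ra fell by 0.82 ± 0.19 (adjusted p = 0.00477; lower in 7 of 7 samples) and Mrc1 by 0.80 ± 0.20. The member that rose was Gata3 (0.51 ± 0.11), a transcription factor of type 2 lymphocytes that keratinocytes also express. Il13 differed by −0.52 ± 0.21 (adjusted p = 0.0945) and Il1b by −0.064 ± 0.39.

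The itch list fell by 0.36 (5 of 13 lower and 1 higher, 5 and 2 adjusted over the list alone; adjusted p = 0.0218 by exact permutation), although adjusted p = 0.647 with an estimated correlation. It shares Tslp and Il4ra with other lists and holds Ltc4s, the leukotriene synthase (−0.66 ± 0.14). The IL-17 and IL-22 list fell by 0.35 (2 of 12 lower and 1 higher, 4 and 1 adjusted over the list alone; adjusted p = 0.0218 by exact permutation), although adjusted p = 0.391 with an estimated correlation. Ccl20, a chemokine of epithelium, fell by 1.35 ± 0.28 and Il19 by 1.02 ± 0.34 (call lost in 10 of the 13 fits without a library). The endothelial list fell by 0.26 (9 of 23 lower, 10 adjusted over the list alone; adjusted p = 0.0396 by exact permutation), although adjusted p = 0.391 with an estimated correlation. The receptor Flt1 was at −0.35 ± 0.07 and its ligand Vegfa at −0.38 ± 0.08. Of the macrophage list 7 of 18 fell and 0 rose (9 and 0 adjusted over the list alone), with C1qa at −0.53 ± 0.11, while the score did not pass (−0.35, exact permutation, adjusted p = 0.0767). In the list of the response to IL-1 and NF-kB 5 of 26 fell and 0 rose, among them Mmp13, Mmp3 and Ccl20. Its score did not pass (−0.40, exact permutation, adjusted p = 0.14).

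The epidermal barrier list rose by 0.30 (15 of 28 higher and 3 lower, 20 and 4 adjusted over the list alone; exact permutation, adjusted p = 0.0218), although adjusted p = 0.391 with an estimated correlation. Its mean score was 8.94 in IL-26 IgG, against 9.27 in BSA IgG, 9.29 in BSA anti-IL-1β and 9.24 in IL-26 anti-IL-1β. Dsg1a rose by 0.75 ± 0.10 (adjusted p = 3.84e-05), Krt1 by 0.58 ± 0.09 and Flg by 0.62 ± 0.16, each higher in 7 of 7 samples. The protease Klk7, which helps shed the outermost cells, fell by 0.62 ± 0.11. The melanocyte and nerve list rose by 0.29 (6 of 14 higher, 9 adjusted over the list alone; adjusted p = 0.0293 by exact permutation), although adjusted p = 0.391 with an estimated correlation. Dct rose by 0.48 ± 0.10. The circadian list rose by 0.31 (7 of 14 higher and 0 lower, 8 and 2 adjusted over the list alone; adjusted p = 0.0218 by exact permutation), although adjusted p = 0.391 with an estimated correlation. The clock-controlled Hlf was at 1.13 ± 0.19, Dbp at 0.82 ± 0.22 and Per3 at 0.59 ± 0.14.

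Among single genes, the decreases with the greatest log2 fold change were in Ecel1, a neuronal peptidase (−2.91 ± 0.37; adjusted p = 3.01e-05), the mucin Muc16 (−2.58 ± 0.45), the keratin Krt36 (−2.13 ± 0.63; call lost without IL-26 IgG replicate 3, adjusted p = 0.0624), Lrtm2 (−1.94 ± 0.28) and Tecta (−1.82 ± 0.33). The greatest increases were in hair keratins and hair keratin-associated genes: Krt26 (4.56 ± 1.17), Krt72 (4.51 ± 1.21), Krt33a (4.19 ± 1.14), Krtap11-1 (3.91 ± 1.12) and Krt81 (3.86 ± 1.04). Only 5 of 7 samples were higher in Krt26, Krt72, Krt33a and Krt81 and 4 of 7 in Krtap11-1. Without IL-26 anti-IL-1β replicate 1 these 4 keratins had log2 fold changes of 2.96, 2.79, 2.03 and 1.85 (adjusted p = 0.0575, 0.0857, 0.153 and 0.139). Krt26 had 5.82 ± 10.8 CPM against 0.254 ± 0.18 in IL-26 ears with IgG. The signs of the median and the score differed for the IL-1 family (−0.064 and 0.020), the IL-26 receptor list (−0.027 and 0.040) and mast cells (0.13 and −0.0056), none of which passed.

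The count of 2828 became 1207 with the small RNA share, 765 with the circadian score and 1054 with the log2 CPM of Cyp24a1 as a covariate, at median ratios of fold changes of 0.994, 0.795 and 0.735, and 2175 to 3506 without a single library. Of the 8 lists, 7 passed with fry, which gave 8 of the 32. Only 3 of the 8 passed without IL-26 IgG replicate 4 and 0 with an estimated correlation. The type 2 and barrier lists lost their calls without that library and the itch list without it or IL-26 IgG replicate 3 (adjusted p up to 0.0673), the endothelial list passed in 2 and the melanocyte list in 5 of the 13 fits without a library.

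**Figure D3:**
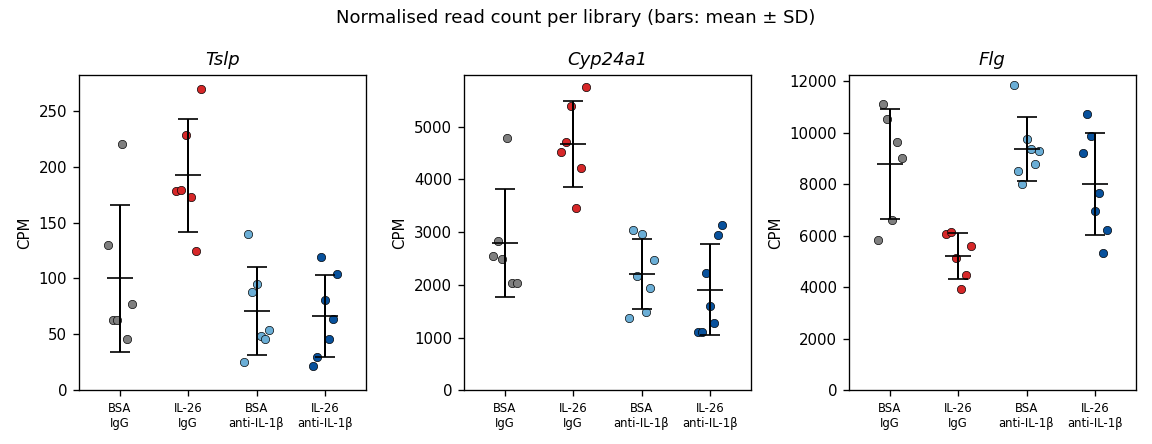
Normalised read count (CPM, y axis) of Tslp, Cyp24a1 and Flg in each library of the 4 groups (x axis); points are libraries and bars are mean ± SD. With IL-26, Tslp was 192 ± 50.4 CPM with IgG and 66.3 ± 36.9 CPM with anti-IL-1β.

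The last comparison, the interaction, asked whether the effect of IL-26 depended on IL-1β. A positive value means that the log2 fold change with IL-26 was lower with IgG than with anti-IL-1β. Serpinb12 was 53.7 CPM with BSA and 15.6 CPM with IL-26 under IgG, against 61.1 and 64.9 CPM under anti-IL-1β. The interaction was 1.87 ± 0.25 (log2; adjusted p = 0.000817; n = 6, 6, 7 and 7). Pitx1 (2.78 ± 0.58), Mt4 (2.75 ± 0.49), Spink7 (2.72 ± 0.62; 3.33 without IL-26 IgG replicate 2), Slurp2 (2.05 ± 0.43), Dsg1a (0.84 ± 0.14) and Krt10 (0.91 ± 0.23) had the same sign. Among the genes with negative values were C1qa −0.77 ± 0.16 (adjusted p = 0.00953), Adgre1 −0.73 ± 0.18, Itgax −0.66 ± 0.11 (adjusted p = 0.00360), Vcam1 −0.68 ± 0.17, Car9 −1.46 ± 0.31 and Ecel1 −2.37 ± 0.52. In edgeR's test 1164 genes passed, 625 positive and 539 negative.

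The type 2 score had an interaction of −0.54 (3 of 21 members negative, 4 adjusted over the list alone; permutation, adjusted p = 0.0258), although adjusted p = 0.417 with an estimated correlation. Il4ra was at −1.05 ± 0.27 (adjusted p = 0.0243) and Mrc1 at −1.08 ± 0.29, calls lost without BSA IgG replicate 2 or 3 (and for Mrc1 without IL-26 IgG replicate 4; adjusted p up to 0.0518 and 0.0604). The macrophage score was at −0.59 (7 of 18 negative, 13 adjusted over the list alone; permutation, adjusted p = 0.0343), although adjusted p = 0.417 with an estimated correlation. The vitamin D response score was at −0.53 (0 of 7 called, 2 negative and 1 positive adjusted over the list alone; permutation, adjusted p = 0.0453), although adjusted p = 0.417 with an estimated correlation. Cyp24a1 was at −0.95 ± 0.35 (adjusted p = 0.102; past the threshold without BSA IgG replicate 4) and Tslp at −1.04 ± 0.55 (adjusted p = 0.259). Positive scores were those of melanocytes and nerve, 0.41 (4 of 14 positive, 7 adjusted over the list alone; permutation, adjusted p = 0.0258), and of immediate-early genes, 0.39 (2 of 16 positive, 8 adjusted over the list alone; permutation, adjusted p = 0.0343), although adjusted p = 0.417 for both with an estimated correlation. Barrier genes did not pass as a list (0.28; adjusted p = 0.0774), with 5 of 28 positive and 1 negative, or 13 and 3 adjusted over the list alone. None of the 21 genes followed in every comparison passed here.

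The count of 1164 was 53 with the circadian score and 15 with the immediate-early score as a covariate, at median ratios of fold changes of 0.814 and 0.994 and with the median standard error up from 0.132 to 0.141 and 0.162. It was 718 without a filter and 2430 with limma. Without a library it was 510, 567 and 652 for BSA IgG replicate 3, BSA IgG replicate 2 and IL-26 IgG replicate 3, 766, 715 and 716 for BSA anti-IL-1β replicates 2, 3 and 7, and 667 and 1943 for IL-26 anti-IL-1β replicates 2 and 5. Of the 5 lists, 0 passed without BSA IgG replicate 3 or BSA anti-IL-1β replicate 4 or 5, and 2 passed with fry. Without BSA anti-IL-1β replicate 6, 11 of the 32 lists passed, with these 5 among them.

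**Figure D4:**
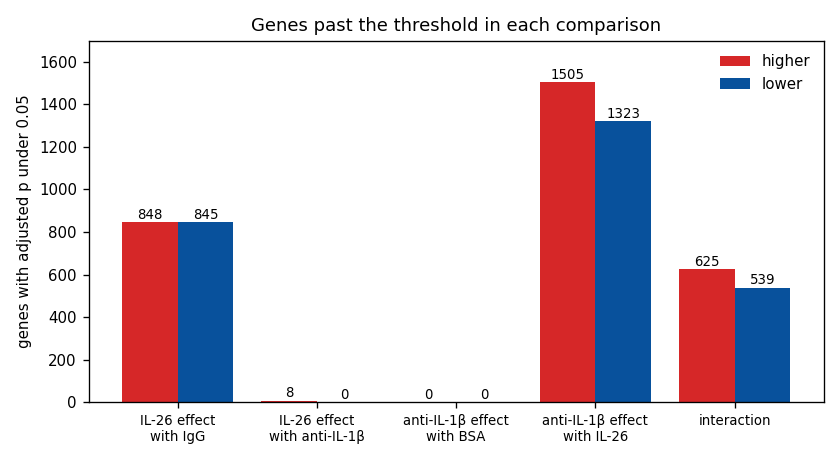
Number of genes with an edgeR adjusted p under 0.05 (y axis), higher and lower, in each of the 5 comparisons (x axis). The counts were 848 and 845 for IL-26 with IgG, 8 and 0 with anti-IL-1β, 0 and 0 for anti-IL-1β with BSA, 1505 and 1323 with IL-26, and 625 and 539 for the interaction.

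The effects of IL-26 in the IgG and the anti-IL-1β samples, which share no library, had a correlation across the 19576 genes of r = −0.071 (rho = −0.13), with a jackknife standard error over libraries of 0.18. Genes are not independent replicates, so no p is given. Of the 1693 genes called with IgG, 571 (33.7%) had the same sign with anti-IL-1β, against 45.5% of all 19576 genes. Those that rose had a median log2 fold change of 0.40 with IgG and −0.055 with anti-IL-1β, and those that fell −0.40 and 0.033. The effects of anti-IL-1β in BSA and in IL-26 ears had r = −0.065 (rho = −0.13, jackknife standard error 0.23). Of the 2828 genes called with IL-26, 1280 (45.3%) had the same sign with BSA, near the 45.5% of all 19576 genes.

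**Figure D5:**
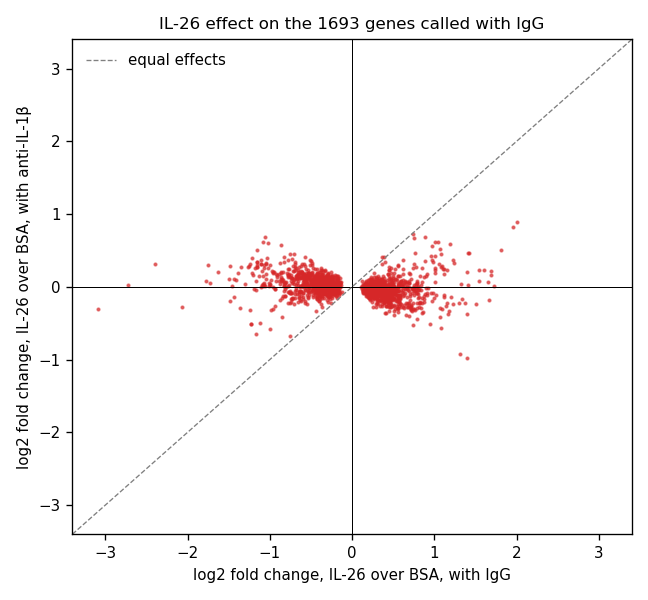
Log2 fold change of IL-26 over BSA with IgG (x axis) and with anti-IL-1β (y axis) for the 1693 genes called with IgG; each point is a gene and the dashed line marks equal effects. The medians of the genes that rose with IgG were 0.40 on the x axis and −0.055 on the y axis.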

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

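The tests of IL-26 IgG replicates 1 and 2 as 1 library and those with the immediate-early score, the circadian score, the small RNA share and Cyp24a1 as covariates were chosen only after the results had been seen; the limits for Cyp24a1, the splits of the samples and the test of the share of epidermis were written before their results.

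The 1693 genes called for IL-26 with IgG were weighed against the near-identical pair of libraries, handling of the ears, time of collection and the amount of MC903 acting in the ear. Chance is unlikely to be the cause: of 40 splits, the real one included, 1 gave as many genes, and the highest other gave 242. With 40 splits a share below 1 in 40 cannot be shown. Counting the pair as 1 library left 1502 genes. The circadian score left the fold changes at a median ratio of 0.933 (1305 genes past the threshold), and the immediate-early score at 0.963, where the count of 13 came from a median standard error that rose from 0.101 to 0.141 at a median size of 0.396 before and 0.378 after. The count of 1502 argues against the pair of libraries as the whole cause. Covariates were fitted to the scatter within groups, so they cannot exclude a handling or an hour that differed between whole groups. With the log2 CPM of Cyp24a1 as a covariate the median ratio was 0.883, and 797 of the 1693 genes were among 1278 called. A response to IL-26 may explain the genes, and differences between the groups in handling, hour or MC903 action stay open.

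The 2828 genes called for anti-IL-1β with IL-26 were weighed against time of collection, RNA preparation and the amount of MC903 acting in the ear. Chance is unlikely to be the cause: 1 of 40 splits, the real one, gave as many genes, and the highest other gave 940. With the circadian score the median ratio of fold changes was 0.795 (0.363 to 0.279 in size, standard error 0.0914 to 0.108), and calls ended because folds shrank and errors rose. With the small RNA share the ratio was 0.994 (standard error to 0.119), and calls ended because errors rose. Both covariates were fitted to the scatter within groups, so neither result can exclude an hour or a preparation that differed between whole groups. In IL-26 ears the small RNA share did not overlap, at 3.682% to 4.941% with anti-IL-1β and 5.034% to 6.695% with IgG. Nor did it in BSA ears, at 4.293% to 5.2% and 5.447% to 6.802%, where 0 genes passed. The genes that rose and fell in IL-26 ears (medians 0.366 and −0.358) had medians of −0.018 and 0.0014 in BSA ears. These values argue against a preparation that differed alike in both anti-IL-1β groups as the main cause. A preparation that differed in IL-26 ears alone stays open. With Cyp24a1, which vitamin D analogues induce, the ratio was 0.735 (quartiles 0.386 and 1.10; size 0.363 to 0.255, standard error to 0.123; 496 of the 1054 genes then called shared), between the limits of 0.25 and 0.75 set in advance. Unequal MC903 action and an effect of the antibody therefore cannot be told apart for these genes, because Cyp24a1 itself differed between the groups and may also respond to the antibody. The reading of MC903 action rests on Cyp24a1 alone. Of the 7 vitamin D response genes 3 fell and 1, Trpv6, rose, and their median log2 fold change was −0.081.

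The higher epidermal barrier score with anti-IL-1β in IL-26 ears was weighed against a larger share of epidermis in the pieces. A list of 12 basal keratinocyte genes, all normally expressed in this tissue, differed by 0.0934 (exact permutation p = 0.0962), against 0.304 for the barrier list. The barrier score minus the basal score differed by 0.21 (exact permutation p = 0.0402, not adjusted). This argues only weakly against a larger share of epidermis as the whole cause. The test was not repeated without IL-26 IgG replicate 4, whose barrier score was 8.59 (others 8.96 to 9.05). A change in differentiation within the epidermis stays open as a hypothesis.

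The effect of IL-26 differed between the antibody groups in 1164 genes. Of 40 splits 1, the real one, gave as many, and the highest other gave 1 gene. These splits reassigned IL-26 and BSA within each antibody group, so they test for no IL-26 effect in either, not for equal effects. With the log2 CPM of Cyp24a1 as a covariate the median ratio of fold changes was 0.885, and 429 of the 1164 genes were among 916 called. Unequal MC903 action stays open for these genes as well. The effect of IL-26 also differed in the scores of type 2 inflammation (−0.542), monocytes and macrophages (−0.588), vitamin D response (−0.527), melanocytes and nerve (0.405) and immediate-early genes (0.39), although adjusted p = 0.417 for each with an estimated correlation. For IL-26 with anti-IL-1β, 1 of 40 splits, the real one, gave as many as 8 genes, and the highest other gave 0. This says little of each of the 8 genes: the count was 0 in a fit of these groups alone and 2 in 6 of the 14 fits without a library. For the 0 genes of anti-IL-1β with BSA in edgeR (1370 at an unadjusted p under 0.05; 0 with DESeq2 and limma) the splits say nothing of chance, since each of the 40 of 40 gives at least 0 genes (highest other 4).

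Single libraries stood apart from their group in 20 of 236 sets of values, where chance gives about 1 in 20, or 11.8. IL-26 IgG replicate 4 had a type 2 score of 5.92 (others 5.08 to 5.39), a cytotoxic score of 1.27 (0.80 to 0.87), a barrier score of 8.59 (8.96 to 9.05) and a vitamin D response score of 4.08 (4.31 to 4.39). IL-26 IgG replicate 3 had a type 1 interferon score of 4.28 (5.37 to 5.47) and an interferon gamma score of 3.90 (4.95 to 5.24). BSA anti-IL-1β replicate 6 had scores of 4.61 for the IL-1 family (4.96 to 5.21), 3.64 for mast cells (4.04 to 4.26) and 0.81 for B cells (1.69 to 2.16), and Ccl17 at 3.58 CPM (1.84 to 2.56). BSA IgG replicate 2 had a hair follicle score of 2.39 (−0.28 to 0.68) and Il1r1 at 68.7 CPM (81.8 to 89.4). BSA IgG replicate 6 had 12.0% of counts on its 10 most abundant genes (10.2% to 10.7%) and 6.80% on small RNA genes (5.45% to 5.71%). The mitochondrial share of BSA anti-IL-1β replicate 4 was 1.75% (1.28% to 1.47%). Il4 was at 2.12 CPM in IL-26 IgG replicate 5 (0.84 to 1.15) and 1.89 CPM in BSA anti-IL-1β replicate 1 (1.12 to 1.45), where Il13 was at 1.33 CPM (0.67 to 0.90). Cxcl1 was at 5.29 CPM in BSA anti-IL-1β replicate 3 (1.23 to 2.51), and Cyp24a1 at 4795 CPM in BSA IgG replicate 4 (2033 to 2834).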

How the results depend on the processing

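The tests with 1 library in place of IL-26 IgG replicates 1 and 2, with protein-coding genes only and with the 4 covariates were chosen only after the results had been seen; all others were planned. Counts within 1.5 times the reported one are not repeated here, except with Cyp24a1 as a covariate, where 797 of the 1693 genes of IL-26 with IgG were among 1278 called (844 higher and 434 lower) and 429 of the 1164 of the interaction among 916. RLE size factors, robust dispersions and a prior count of 0.5 left every count of genes or lists within that range. Of the named genes called, 218 of 220 kept their call and direction with RLE size factors, 220 with DESeq2, 207 with limma, 195 without a filter, 92 with Cyp24a1, 98 with the circadian score, 78 with the immediate-early score and 183 with the small RNA share. Depth was 17114364 to 33541991 counts and was not varied; it limits what can be said of the genes among 56200 that fell outside the 19576 tested. Simulated changes of 1.5-fold were recovered in 47% to 76% of genes.

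Without single libraries the counts of genes ranged from 824 to 2590 for IL-26 with IgG, 2 to 75 for IL-26 with anti-IL-1β, 0 to 7 for anti-IL-1β with BSA, 2175 to 3506 for anti-IL-1β with IL-26 and 510 to 1943 for the interaction; the lists ranged from 0 to 9, 0 to 0, 0 to 0, 3 to 11 and 0 to 11. The correlations across genes ranged from −0.14 to 0.027 between the effects of IL-26 and from −0.17 to 0.061 between those of anti-IL-1β.

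For IL-26 with IgG the count was 3552 with limma (1678 of the 1693 shared) and 13 with the immediate-early score, where standard errors rose. For IL-26 with anti-IL-1β it was 4 without a filter, 154 with DESeq2, 70 with limma, 0 in a fit of these groups alone, which has fewer samples, 4 with the pair as 1 library, 1 among protein-coding genes, and 0, 2 and 127 with the circadian score, the small RNA share and Cyp24a1. For anti-IL-1β with IL-26 it was 765, 1207 and 1054 with the same covariates. For the interaction it was 718 without a filter, 2430 with limma, 53 with the circadian and 15 with the immediate-early score. Apart from the reasons given, the cause was not tested. Counts of lists for IL-26 with IgG were 12 with a preset and 0 with an estimated correlation and 10 with fry; with a preset correlation they were 9 for IL-26 with anti-IL-1β and 12 for anti-IL-1β with BSA. Those for anti-IL-1β with IL-26 were 0 with an estimated correlation, and those for the interaction 3 with z scores, 18 with a preset and 0 with an estimated correlation, and 2 with fry; the cause was not tested. With the pair as 1 library they were 2, 7 and 4 for IL-26 with IgG, anti-IL-1β with IL-26 and the interaction. Effects turned to the other sign for Fosb in IL-26 with IgG with the immediate-early score, which contains it (0.0189), and for anti-IL-1β with IL-26 with Cyp24a1 as a covariate for Tslp (0.17), Stfa1 (0.14), Ptges (0.0571), F2rl1 (−0.0742), Krt83 (−0.0659) and, by construction, Cyp24a1 itself (7.69e-06).

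With the replicate number as a block, the lists past the threshold were 0 for IL-26 with IgG, 0 for anti-IL-1β with IL-26 and 4 for the interaction. IL-26 with IgG and anti-IL-1β with IL-26 had 6 same-numbered pairs each. An exact test within so few pairs cannot give a p small enough for a few lists to pass the adjustment. Their counts of 0 therefore do not show whether the lists depend on the block. No count of genes moved by over 1.5 times, although 3 of the 8 genes of IL-26 with anti-IL-1β were among the 8 then called. Same-numbered samples had mean correlations of −0.023, 0.10, −0.032 and 0.084 in the 4 comparisons of groups, 1 to 3 samples per comparison correlated best with their own number, and 2 of 6, 4 of 7, 1 of 6 and 3 of 6 pairs were over 0.1. Samples of other numbers had mean correlations of 0.0050, −0.017, 0.0073 and −0.016. Not every same-numbered pair was over 0.1, so the samples were taken to share only a number. These values cannot exclude that some same-numbered samples came from 1 animal.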

Other observations

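The tests with the circadian score as a covariate were chosen only after the results had been seen; the single genes in the next 2 paragraphs come from the planned test.

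Of 18 matrix genes 4, and of 23 endothelial genes 5, rose with IL-26 under IgG and 0 fell, and neither list passed (exact permutation, adjusted p = 0.139 and 0.126). Fibronectin (Fn1) rose by 0.82 ± 0.14 (log2; edgeR adjusted p = 0.000996), the fibroblast receptor Pdgfra by 0.48 ± 0.12, the endothelial cadherin Cdh5 by 0.51 ± 0.115 and the vessel peptide Apln by 0.84 ± 0.19. The matrix proteases Mmp13 and Mmp3, outside both lists but in that of the response to IL-1 and NF-kB, rose by 1.39 ± 0.35 and 0.80 ± 0.18. With anti-IL-1β in IL-26 ears, Fn1 fell by 0.64 ± 0.13, Mmp13 by 1.81 ± 0.34, Mmp3 by 0.83 ± 0.17 and Apln by 0.87 ± 0.18, each lower in 7 of 7 samples. Both comparisons use the same 6 IL-26 IgG libraries, so genes chosen for a rise in the first tend to fall in the second by selection alone. The interaction, which uses these libraries too, passed for Fn1 (−0.68 ± 0.19), Mmp3 (−0.84 ± 0.24), Mmp13 (−1.76 ± 0.48) and Cdh5 (−0.53 ± 0.16), and not for Apln or Pdgfra. These 4 calls were lost in 9, 17, 8 and 18 of the 26 fits without a library (adjusted p up to 0.0660, 0.0819, 0.0644 and 0.0882).

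Of 16 mast cell and basophil genes 3 rose and 1 fell with anti-IL-1β in IL-26 ears: Hpgds, a prostaglandin synthase, rose by 0.46 ± 0.08 (adjusted p = 0.000605) and the basophil protease Prss34 fell by 1.42 ± 0.34 (adjusted p = 0.00553), each in 7 of 7 samples. Of 22 hair follicle genes 11 rose and 2 fell (17 and 2 adjusted over the list alone), while the score of 0.74 did not pass (exact permutation, adjusted p = 0.636). Without IL-26 anti-IL-1β replicate 1 the calls of Krt72, Krt33a, Krt33b, Krt34, Krt81, Krt83 and Krt86 were lost (adjusted p = 0.0857, 0.153, 0.215, 0.333, 0.139, 0.183 and 0.169). The members that fell were Tchh, a protein of the inner root sheath, at −1.61 ± 0.29 and the transcription factor Hoxc13 at −1.05 ± 0.19, both lower in 7 of 7 samples, and Foxn1 rose by 0.53 ± 0.11.

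The first 2 principal components of the 1000 most variable genes held 21.2% and 13.2% of the variance.

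The circadian score in IL-26 ears differed with the antibody by 0.31, although adjusted p = 0.391 with an estimated correlation. With that score as a covariate the interaction kept 49 of its 1164 genes among 53 called, while its fold changes had a median ratio of 0.814 (size 0.527 to 0.409, standard error 0.132 to 0.141), so that the calls ended because folds shrank and errors rose. A candidate explanation is a different hour of collection of the groups, which the labels do not give. The median ratio of fold changes of 0.795 for anti-IL-1β with IL-26 cannot exclude it, because the covariate was fitted to the scatter within groups.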
